A study of Mus musculus with 43 samples.

How the data were processed

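Per the labels, the samples are mouse astrocytes, and RNA was sequenced from stranded poly(A) libraries on an Illumina instrument with single-end reads of 50 bp. The submitters' processing notes name FastQC 0.11.8, STAR 2.5.3a, HOMER 4.10.4 and DESeq2 1.14.1 with the mouse build mm10, without saying which tool made which column. The authors deposited 3 tables of 24537 genes each, for WT, FXS, RTT and DS (22 libraries), for BMP6 and Alone (12 libraries) and for the preparations IP acute, IP cultured and MD cultured (9 libraries). Expression in the first 2 tables is FPKM per the file headers. The preparation table's header names no unit, and its values were read as FPKM deposited by the authors because its layout is the same. The preparation table also holds log2 fold changes computed by the authors for 3 comparisons, and the adjusted p-values deposited with them, which are 1 wherever no fold change is given. Values were rounded to 3 decimals by the authors, and sums of FPKM per library differ between tables (305262 to 401658.7 in the first 2 and 605761 to 637271 in the last), so levels were compared only within a table.

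Groups were taken from the labels, which give the disorder and not the mouse strain, and call the disorder and BMP6 samples biological replicates. For the preparation table nothing says that the libraries came from separate cultures, so p-values there measure the spread between these samples. All libraries of the disorder table carry the batch label 1, those of the preparations the label 8, and the BMP6 and Alone libraries of each culture share a batch label of their own.

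Depth was estimated from the values: where whole reads are counted, the low values of a gene are whole multiples of what 1 read is worth. Between 75.4% and 81.0% of low values came out whole within 0.08 of a read, against 3.7% to 8.2% at other depths (median). Since the lengths behind the FPKM are not given and not all values came out whole, no count test was run. Libraries had 11820 to 13814 genes at an FPKM of at least 1, and the 20 genes of highest FPKM took 7.8% to 19.7% of the sum. Within groups, libraries correlated at r = 0.875 to 0.991, and at most 2.33% of values above 0 were identical between any 2 libraries.

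Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a trend) on log2(FPKM + 0.5), in a fit per table with the group as the only factor. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the genes tested, and an adjusted p under 0.05 was the threshold. Genes needed an FPKM of at least 1 in at least as many libraries as the smallest group of the table (4, 6 and 3). Fold changes are on the log2(FPKM + 0.5) scale and understate the change of low genes. A gene listed at 0 in all libraries of a group is given no fold. Groups are said not to overlap where every library of a group lies above every library of the other. The median of the chromosome 16 and 17 lists in DS was tested by exact permutation of the DS and WT labels (210 splits, two-sided).

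Gene lists were tested with limma's camera at the preset inter-gene correlation of 0.01 and with the correlation estimated from the data, adjusted over the lists of a comparison; members past the threshold were counted over all genes and also adjusted over the list alone. The 24 lists covered the triplicated Ts65Dn segments of chromosomes 16 and 17, astrocyte, microglial, oligodendrocyte precursor, oligodendrocyte, neuronal, endothelial, and mural and fibroblast markers, BMP targets, BMP ligands, receptors and antagonists, the IGF axis, secreted synapse-regulating genes, pan-reactive, A1 and A2 genes, cell cycle, immediate early and stress genes, cholesterol synthesis, glycolysis and hypoxia, extracellular matrix, SRF and YAP targets with serum-induced cytoskeletal genes, interferon response, and sex-linked genes. That the Down syndrome model is Ts65Dn was an assumption. Lists, comparisons, tests and the alternatives in the next paragraph but for those said to be added were fixed before the data were examined, as was the rule for naming genes. The rule names the targeted genes (Fmr1, and App, Sod1, Dyrk1a and Son of the triplicated segment), Bmp6, Igfbp2 and Smoc1 in the disorders, Id1, Id3 and Smad6 for BMP6, and Gfap, Aqp4, Slc1a2 and Aldh1l1 for the preparations. It adds the 10 largest rises and 10 largest falls past the threshold with a mean FPKM of at least 2 and no overlap, or the 5 of smallest p where fewer than 5 pass. From each list that passes it takes up to 4 members of smallest p, and from the genes called in a disorder and with BMP6 up to 10 of the same sign. Genes without an established name were skipped. Some genes that the rule names are not reported here.

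Alternatives were pseudocounts of 0.1 and 1, no filter on low values, a filter at an FPKM of 5, scaling by the median of ratios, quantile normalization, a fold change of at least 2, robust empirical Bayes, only the 2 groups compared in the fit, the replicate number as a block, an estimated correlation, and leaving out each replicate. Added after the data were seen were array weights, leaving out libraries or cultures that stood apart (WT 33, FXS 31 and DS 32; 2 BMP6 cultures; IP cultured 4), Ddx3y, the cell cycle mean or the mean of ciliated cell genes as a covariate, the pseudocounts and scalings for the comparisons between disorders, and a list of 15 genes of ciliated cells.

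Sharing of WT libraries between disorders was examined with 100 simulations of unchanged groups set against a shared control group. In these, the deviations of all 22 libraries from their group means were shuffled over the groups with random sign. The WT libraries were also divided into sets of 3 in 20 ways. The method was tested on simulated data, drawn for each gene independently from its mean and spread in these tables, with known changes put in. Genes do not vary together in such data, unlike here, so the shares recovered and false hold for such data only. A 2-fold change was recovered in 91.0% of genes for FXS, 89.6% for RTT, 86.6% for DS, 76.1% for BMP6, and 43.3% to 50.7% for the preparations, and 2.41% to 8.91% of calls were false. Positions are those of GENCODE M21 on mm10 (23828 symbols). To find genes that share sequence, 1899043 stretches of 50 bp, taken every 25 bp from 12502 genes, were aligned with bwa 0.7.19 with up to 2 mismatches; H2-Q8, AA388235 and Dscr3 were not searched. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15. Raw reads were not used here.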

Results

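RNA was sequenced from mouse cortical astrocytes, the glial cells that take up glutamate and secrete factors acting on neurons. Cells of the first set came from the cortex at postnatal day 7, were purified by immunopanning (capture on antibody-coated dishes) and were grown for 12 days in medium free of serum. The set covered wild-type mice (WT, n = 6) and models of 3 neurodevelopmental disorders, Fragile X syndrome (FXS, n = 6), Rett syndrome (RTT, n = 6) and Down syndrome (DS, n = 4). The next set held WT cultures given the secreted factor BMP6 over the last 5 days (n = 6) beside untreated sister libraries (Alone, n = 6). The remaining 9 libraries compared astrocytes immunopanned and lysed at once (IP acute, n = 3), immunopanned and cultured (IP cultured, n = 3), and cultured by the preparation that the labels call MD (MD cultured, n = 3). Depth estimated from the steps of the lowest values ran from 10.2 to 55.5 M reads over the 43 libraries (median 27.1 M). It was lowest in WT (median 18 M, 10.2 to 36.1), against 44.6 M in FXS (16.4 to 55.5), 36.1 M in RTT (31.1 to 47.0) and 31 M in DS (25.7 to 37.7). Medians were 27.8 M in Alone, 28.2 M in BMP6, 20.9 M in IP acute, 20.8 M in IP cultured and 20.2 M in MD cultured.

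The FXS comparison asked how astrocytes of the Fragile X model differ from WT. Fmr1, the gene silenced in the syndrome (chromosome X, 68678541 to 68717963, mm10), lay between 0.967 and 2.21 FPKM in the 6 FXS libraries and between 12.0 and 17.1 FPKM in the 6 WT libraries. It fell by 2.81 on the log2 scale (SE 0.15, adjusted p = 1.1e-10), and by limma no other gene of the 12780 tested passed the threshold. With only WT and FXS in the fit, an alternative set beforehand, 209 of 12304 genes passed. At an unadjusted p under 0.05 there were 2493 genes, where 639 are expected of independent tests without a difference. The number was 1601 without FXS 17, and 943 with the mean of ciliated cell genes, a list added after the data were seen, as a covariate. The genes with the smallest p short of the threshold (adjusted p = 0.0627 for each) included the lower Ltbp1 (log2 -1.24, SE 0.22) and Timp1 (-1.34, SE 0.25), which act on TGF-beta storage and matrix proteases. The others were the lower Glycam1 (-1.69, SE 0.32) and Gpc5 (-1.48, SE 0.28), and the higher Dpf1 (0.48, SE 0.09). Bmp6 averaged 136.6 FPKM ± 20.6 (SD, n = 6) in FXS and 81.5 ± 20.6 in WT, a log2 difference of 0.77 (SE 0.20) with an adjusted p of 0.105. Igfbp2 (adjusted p = 0.74) and Smoc1 (adjusted p = 0.443) differed by less than the spread between cultures. Leaving out single libraries moved the number of genes past the threshold to 14 without WT 22, 3 without WT 30, 2 without FXS 28 and 5 without FXS 38.

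As groups, cholesterol synthesis genes were higher in FXS in all 24 members measured, with a median log2 difference of 0.32 (camera adjusted p = 6.25e-09). Among them were Hmgcs1 (0.49, SE 0.13), Stard4 (0.45, SE 0.12) and Sqle (0.24, SE 0.08). BMP target genes were also higher (17 of 22, median 0.30, adjusted p = 0.00184), among them Smad9 (0.62, SE 0.18), Id3 (0.72, SE 0.22) and Zcchc12 (0.92, SE 0.29), while Bmper was lower (-0.84, SE 0.18). Genes of ciliated cells summed to 831 FPKM ± 440 (SD, n = 6) in FXS and 375 ± 177 in WT, and with their mean as a covariate the median of the BMP targets was 0.20 (15 of 22 higher, adjusted p = 0.0171). Astrocyte markers were lower in 30 of 38 (adjusted p = 0.000828), including the transporters Slc7a10 (-0.92, SE 0.20) and Slc1a2 (-0.76, SE 0.19) and the claudin Cldn10 (-0.96, SE 0.24). The pan-reactive list was lower in 11 of 12 (adjusted p = 0.00069), with Serpina3n at -1.46 (SE 0.32), Steap4 at -1.04 (SE 0.29) and Osmr at -0.58 (SE 0.19). Mural and fibroblast genes such as Mgp (-1.45, SE 0.33), Rgs5 (-1.65, SE 0.52), Vtn (-1.92, SE 0.64) and Col3a1 (-0.89, SE 0.35) were lower in 17 of 19 (adjusted p = 0.0016). So were all 11 microglial genes (median -0.93, adjusted p = 0.000582), Cd68, Fcrls, C1qc and C1qa among them. None of these 6 lists held with an estimated correlation (adjusted p = 0.487 for cholesterol synthesis, BMP targets, astrocyte and pan-reactive genes, 0.631 for the mural and microglial ones). The FXS and WT libraries were also split in 100 ways, the real one included. Medians as large came from 3 splits for cholesterol synthesis and 2 each for BMP targets, astrocyte and pan-reactive genes. They came from 17 for mural and 12 for microglial genes. Adjusted over the list alone, 2 cholesterol genes were higher, 11 BMP targets were higher and 3 lower, 6 astrocyte genes were lower, 5 pan-reactive genes were lower and 1 higher, and 3 mural genes were lower, against 0 over all genes tested. Without WT 33, FXS 31 and DS 32 the microglial and mural lists no longer passed (adjusted p = 0.0763 and 0.0906), and the cholesterol median was 0.20 (camera adjusted p = 0.00224). The microglial list was also lost without WT 30 (adjusted p = 0.089) or WT 33 (0.143) alone. Passing only with a library left out were the lower oligodendrocyte list (without FXS 17, FXS 29, WT 22, WT 26, WT 34 or WT 35; adjusted p = 0.0071 to 0.0464) and A1 list (FXS 17, WT 22, WT 26, WT 34 or WT 35; 0.00248 to 0.0464). So did the lower matrix list (FXS 38; 0.017) and the higher interferon list (FXS 28; 0.039). The other 18 lists did not pass (adjusted p = 0.062 to 0.998), the highest being the IGF axis (16 genes, median log2 0.04, mean -0.05).

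The same question was put for the Rett model (n = 6 against 6). Of the 12780 genes tested 1 passed the threshold, and 1342 had an unadjusted p under 0.05, where 639 are expected of independent tests without a difference. That number was 2110 without WT 22, 874 without WT 33 and 848 without WT 34. Short of the threshold, the genes of smallest p were the higher Sh3bp4 (log2 0.53, SE 0.10, adjusted p = 0.123) and the lower Serinc2 (-1.10, SE 0.21, adjusted p = 0.166). Also lower were Xist (-3.21, SE 0.64, adjusted p = 0.166), Crym (-0.83, SE 0.19) and Cntnap2 (-0.84, SE 0.20, adjusted p = 0.47 for each). Xist, transcribed from the inactive X chromosome, stayed at or under 0.012 FPKM in all 6 RTT libraries. Ddx3y, a Y-linked gene chosen after its values were seen, lay between 8.78 and 12.4 FPKM in them, so these cultures held male cells, whereas 5 of 6 WT libraries had Xist at 2.85 FPKM or more. Ddx3y lay between 2.70 and 10.4 FPKM in the 6 WT libraries, so WT cultures held male cells too. The sex of the cultures thus differed in part between RTT and WT, and its effect cannot be told apart from that of the model. With Ddx3y as a covariate, 867 genes had an unadjusted p under 0.05. Bmp6 averaged 103.5 FPKM ± 33.2 (SD, n = 6; adjusted p = 0.516), and neither Igfbp2 (adjusted p = 0.893) nor Smoc1 (adjusted p = 0.852) differed beyond the spread. Microglial genes were lower in 10 of 11 (median log2 -1.23, camera adjusted p = 2.81e-07), among them Tyrobp (-1.70, SE 0.47), C1qa (-1.69, SE 0.49), Fcrls (-1.43, SE 0.41) and Mpeg1 (-1.14, SE 0.35). That result did not hold with an estimated correlation (adjusted p = 0.728), and 9 of its members were lower when adjusted over the list alone against 0 over all genes. As large a median came from 4 of 100 splits of the RTT and WT libraries, the real one included. The other 23 lists did not pass (adjusted p = 0.127 to 0.849). With a library left out, cell cycle genes passed as lower (without RTT 40, RTT 44, WT 30, WT 33 or WT 34; adjusted p = 9.56e-07 to 0.0206) and BMP targets as higher (RTT 43, RTT 44 or WT 30; 0.0206 to 0.0332). Also higher were the immediate early (RTT 40 or WT 33), synapse-regulating (RTT 40), cholesterol (WT 30) and SRF and YAP lists (WT 33), at 0.00102 to 0.0333, and lower was the mural list (RTT 43; 0.0332). Without WT 22 the genes past the threshold numbered 4, and without WT 33 they numbered 2.

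**Figure D1:**
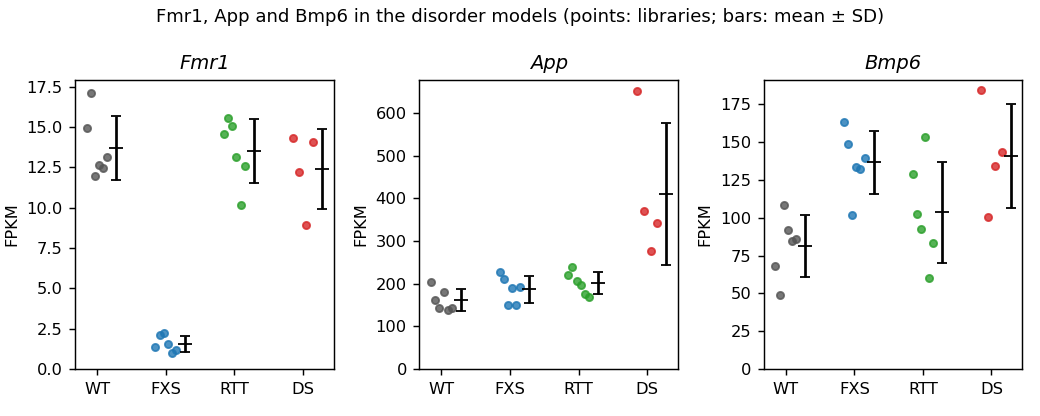
FPKM of Fmr1, App and Bmp6 in each library of WT (n = 6), FXS (n = 6), RTT (n = 6) and DS (n = 4), with points for libraries and bars for the mean ± SD. Fmr1 averaged 1.56 FPKM in FXS and App 409.8 FPKM in DS, apart from WT in every library.

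The Down syndrome comparison first asked whether genes of the chromosome segments triplicated in the Ts65Dn model, a strain the labels do not name and which was assumed beforehand, were expressed above WT. On chromosome 16 (84717576 to 97962622, mm10) 61 of 66 listed genes were higher in DS (n = 4) than in WT (n = 6), at a median log2 difference of 0.45, a ratio of 1.36 where 3 copies predict 1.5. Exact permutation of the labels put that median at p = 0.00476, with 1 of 210 splits as large and the next highest at 0.33. Of the list, 27 genes rose and 0 fell (39 and 0 adjusted over the list alone), and the list passed the camera test with the preset correlation (adjusted p = 1.12e-30) and with an estimated one (adjusted p = 1.69e-07). App, the amyloid precursor gene (84949685 to 85173766), averaged 409.8 FPKM ± 166 (SD) against 161.4 ± 25.9, a log2 rise of 1.28 (SE 0.18, adjusted p = 0.000141). Jam2 (0.89, SE 0.11), Tmem50b (0.89, SE 0.12), Dscr3 (0.72, SE 0.10) and the calmodulin regulator Pcp4 (2.27, SE 0.35) rose as well, although 33.3% of the Pcp4 transcript matched other genes and its level is uncertain. Dyrk1a rose by 0.39 (SE 0.09, adjusted p = 0.018), a call lost under 5 of 20 alternatives, while Sod1 (0.55, SE 0.18, adjusted p = 0.0854) and Son (0.14, SE 0.18, adjusted p = 0.698) did not pass. The proximal end of chromosome 17 behaved alike, with 17 of 18 listed genes higher (median log2 0.45, exact permutation p = 0.00476, next highest split 0.43). Past the threshold, 4 genes rose (11 adjusted over the list alone), among them Ezr (0.99, SE 0.20), Tfb1m (0.55, SE 0.10) and Serac1 (0.62, SE 0.13). Tmem181a was the exception, with a fall of -0.64 (SE 0.11) in a gene that shares 24.4% of its sequence with others. In the chromosome 16 interval 38.6% of 70 tested genes passed the threshold, in the chromosome 17 interval 26.1% of 23, and elsewhere 4.12% of 12687. Calls elsewhere were not spread evenly. Chromosome 17 as a whole had 55 of 608 genes past the threshold (9.05%), only 6 of them in the interval. Chromosome 16 outside its interval had 10 of 326 (3.07%).

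**Figure D2:**
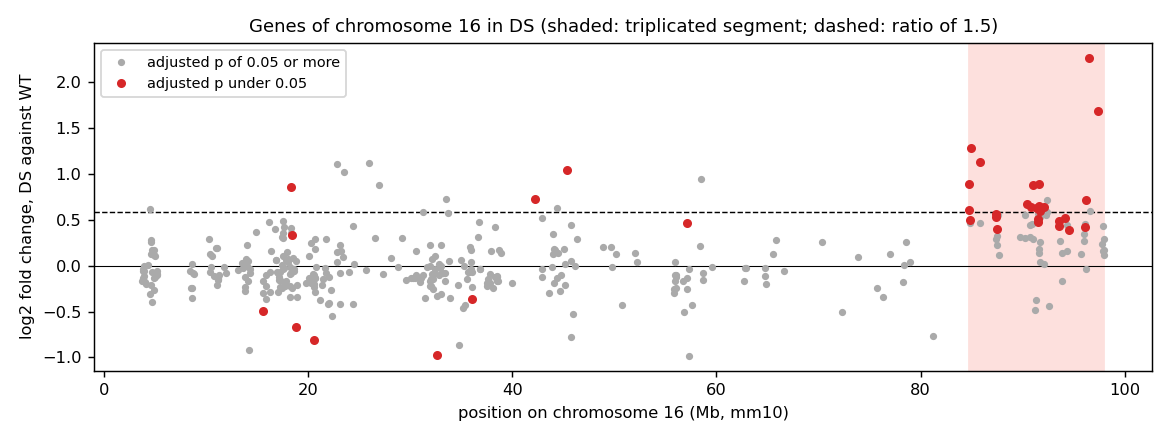
Log2 fold change of DS (n = 4) against WT (n = 6) for each tested gene on chromosome 16, by position in Mb (mm10), with genes of adjusted p under 0.05 in red, the triplicated segment shaded and a ratio of 1.5 as a dashed line. The shaded segment holds 70 tested genes, of which 27 rose and 0 fell.

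Across the genome 556 of 12780 genes differed in DS, 269 higher and 287 lower. Over all tested genes, the libraries of the groups did not overlap in 792 (6.20%, against 0.952% by chance). Higher genes made up 48.4% of the 556, and 62.0% or 62.3% after median-of-ratios or quantile scaling. Large rises outside the segments were Syt1, a synaptic vesicle gene (log2 3.49, SE 0.32), AA465934 (3.93, SE 0.22) and the endosomal adaptor Wdfy1 (3.08, SE 0.14, from 1.66 FPKM ± 0.174 to 17.7 ± 1.31). Others were the calcium channel subunit Cacng6 (2.61, SE 0.15) and the ribonuclease Rnase1 (2.38, SE 0.44). Gbp2b and Ifi202b, interferon-inducible genes listed at 0 in all 6 WT libraries, averaged 5.47 FPKM ± 0.893 and 2.32 ± 0.818 (SD, n = 4) in DS. Among the falls were the chaperone Hspa8 (-3.12, SE 0.19, 15.2 FPKM ± 9.13 against 123.1 ± 10.1), Atp6v0c (-2.58, SE 0.41) and AA388235 (-2.14, SE 0.30). The apoptosis gene Pmaip1 (-2.02, SE 0.29) and the glutamate receptor Grm5 (-1.95, SE 0.48) fell too, the last call being lost under 5 of 20 alternatives. Rises of H2-Q2, H2-Q6 and H2-Q8 and falls of Rps18, Rps2, Rpl3, C4b and Hspa8 are uncertain, since these genes have near-identical copies that the counting can confuse (58.5% of H2-Q6 and 59.2% of Hspa8 matched elsewhere). Bmp6 averaged 140.8 FPKM ± 34.6 (SD, n = 4), a log2 rise of 0.80 (SE 0.23) at an adjusted p of 0.0492, which 14 of 20 alternatives lost (adjusted p = 0.0313 to 0.378 over the 20). Igfbp2 (adjusted p = 0.914) and Smoc1 (adjusted p = 0.441) did not differ beyond the spread. The count of genes past the threshold depended on single libraries, at 256 without DS 19 and 894 without DS 32, and on the fit, at 305 with only WT and DS in it. With the mean of cell cycle genes as a covariate, chosen after the data were seen, it was 164, of which 152 were among the 556. With Ddx3y as a covariate, also chosen then, 472 genes passed. Sex-linked genes summed to 13.7 FPKM ± 5.96 (SD, n = 4) in DS and 22.3 ± 6.88 (n = 6) in WT. Whether the sex of the cultures differed between these groups was not settled, since the sex-linked list did not pass with all libraries.

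Cell cycle genes were lower in DS in all 42 members (median log2 -0.80, camera adjusted p = 2.67e-15), 16 of them past the threshold over all genes and 32 adjusted over the list alone. Among these were Rrm1 (-0.66, SE 0.13), Bub1b (-1.08, SE 0.26), Mcm2 (-0.75, SE 0.18) and Mcm7 (-0.61, SE 0.15, with 61.5% of its sequence shared). Without DS 19 the calls of Bub1b, Mcm2, Mcm7 and Id3 were lost. Interferon-response genes were higher in 29 of 33 (adjusted p = 1.79e-10; 5 past the threshold, 7 adjusted over the list alone), including Ifi44 (1.03, SE 0.23), Bst2 (1.15, SE 0.30), Psmb9 (0.80, SE 0.21) and Stat2 (0.61, SE 0.17). BMP targets were higher in 16 of 22 (adjusted p = 6.28e-05), where Smad9 (0.98, SE 0.20) and Id3 (1.09, SE 0.25) rose and Ror2 (-0.72, SE 0.20) fell, 10 higher and 1 lower adjusted over the list alone. Oligodendrocyte genes were higher in all 11 (adjusted p = 0.00161; Mal at 1.24, SE 0.34, with 2 higher adjusted over the list alone). The neuronal list passed (adjusted p = 0.042) without moving as a group, since 7 of 13 members were higher at a median log2 of 0.04. It was carried by 3 genes past the threshold (3 adjusted over the list alone), Syt1, Gad1 (1.60, SE 0.22) and Gap43 (0.73, SE 0.21). The calls of Bst2, Psmb9, Stat2, Ror2, Mal and Gap43 were lost under 7, 7, 10, 8, 9 and 13 alternatives. Microglial genes were lower in 10 of 11 (adjusted p = 0.0215; 0 past the threshold). Single libraries decided 3 of these lists. The neuronal list was lost without DS 21, DS 39, WT 30, WT 33 or WT 34 (adjusted p = 0.0594 to 0.149). The microglial list was lost without DS 39, WT 30, WT 33 or WT 34 (0.188 to 0.745), and the oligodendrocyte list without DS 21 (0.101) or DS 32 (0.0501). Of these lists only the chromosome 16 and 17 segments held with an estimated correlation. The adjusted p was then 0.324 for cell cycle, interferon and neuronal genes, 0.107 for BMP targets, 0.535 for oligodendrocyte and 0.811 for microglial genes. Of 100 splits of the DS and WT libraries, 2 gave as large a median for cell cycle and for interferon genes and 4 for BMP targets. As large a median came from 34 splits for oligodendrocyte, 74 for neuronal and 16 for microglial genes. The 16 further lists did not pass (adjusted p = 0.0655 to 0.926). Mural genes passed as lower without DS 19, DS 21, WT 22 or WT 26 (adjusted p = 0.00957 to 0.0403), as did the matrix (0.0442) and sex-linked lists (0.0142) without DS 19, and the A1 list passed as higher without DS 39 (0.0492).

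The disorders were next set against each other. Between RTT and FXS 3 genes passed the threshold, among them Fmr1 (log2 2.79, SE 0.15) and the methyltransferase As3mt (0.51, SE 0.09, adjusted p = 0.0422). The last was lost after either scaling. An unadjusted p under 0.05 was found for 1794 genes. DS differed from FXS in 347 genes (196 higher) and from RTT in 350 (196 higher), with Wdfy1, Gbp2b, Cacng6 and App among the genes higher in DS in each case. After median-of-ratios scaling the higher share moved from 56.5% to 67.6% against FXS and from 56.0% to 66.7% against RTT, and after quantile scaling to 69.0% and 64.5%. The astrocyte marker S100b was higher in DS than in FXS (1.60, SE 0.30) and Cbs was lower (-1.23, SE 0.21), and the interferon genes Psmb9 (1.11, SE 0.21) and Ifi44 (0.96, SE 0.23) were higher in DS than in RTT. Cholesterol synthesis genes were lower than in FXS in all 24 members, in RTT (camera adjusted p = 4.8e-07) as in DS (adjusted p = 1.9e-06), with Hmgcs1 at -0.47 (SE 0.13) in RTT and Cyp51 at -0.71 (SE 0.16) in DS. Secreted synapse-regulating genes were higher in RTT than in FXS in 31 of 43 (adjusted p = 0.00458, with 1 higher adjusted over the list alone). Sex-linked genes were lower in DS than in RTT in 4 of 5 (adjusted p = 0.014), Eif2s3y by -2.94 (SE 0.45). Their sums ran from 27.6 to 40.3 FPKM in RTT and from 8.43 to 19.9 in DS. The RTT cultures held male cells with Xist nearly absent. In comparisons with RTT the sex of the cultures and the disorder therefore cannot be told apart. In all, 8 of 24 lists passed for RTT against FXS, 9 for DS against FXS and 8 for DS against RTT. With an estimated correlation 0, 2 and 2 did, the pairs being the triplicated segments.

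Whether the disorders share changed genes could not be read from the calls, since FXS and RTT had 1 gene each past the threshold by limma. The count of 0 genes in the same direction in any pair was thereby nearly fixed. It was 9 without RTT 40, 7 without WT 22, 2 without DS 19, and 1 without WT 30, DS 21, DS 32 or FXS 38. Unchanged groups simulated against a shared control group gave 3.56 on average and 351 at most. Fold changes across genes, which are not independent replicates, correlated at r = 0.431 between FXS and RTT (0.502 simulated with no effect), 0.538 between FXS and DS (0.462) and 0.342 between RTT and DS (0.479). With the WT libraries split so that each disorder had its own 3 controls the mean values were 0.225, 0.364 and 0.152. The covariances were 0.0304, 0.0576 and 0.026, against 0.018, 0.0184 and 0.0191 simulated on average and 0.0783, 0.0778 and 0.0826 at most, so each lay within the range found without an effect.

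The BMP6 comparison asked what this ligand, which signals through SMAD proteins, does to WT astrocytes. The SMAD-driven genes Id1 (78.8 FPKM ± 32.6 to 236.8 ± 18.4, log2 1.69, SE 0.25, adjusted p = 0.00183) and Id3 (117.1 ± 54.8 to 587.7 ± 63.2, log2 2.44, SE 0.25) rose in 6 of 6 cultures. So did Smad6 (3.2 ± 1.39 to 16.7 ± 3.35, log2 2.29, SE 0.26), Smad7 (1.92, SE 0.20) and Smad9 (1.74, SE 0.19). Myoc, which encodes the secreted protein myocilin, rose furthest, from 0.134 FPKM ± 0.0928 to 16.5 ± 7.01 (log2 4.65, SE 0.26, adjusted p = 2.86e-06). Among genes without overlap it was followed by the lipid droplet gene Cidea (4.01, SE 0.32), the secreted Serpinf1 (3.86, SE 0.30), Pcp4 (3.48, SE 0.22) and Tmem158 (3.30, SE 0.43). Next came the cholesterol acyltransferase Lcat (3.22, SE 0.38), Hspb8 (3.2, SE 0.54), the BMP antagonist Nog (3.06, SE 0.36), Ptchd2 (3.03, SE 0.43) and Fxyd6 (2.77, SE 0.44). Smoc1, a secreted BMP antagonist, fell furthest, from 26.6 FPKM ± 22.8 to 2.31 ± 0.808 (log2 -2.85, SE 0.52, adjusted p = 0.0055). Pde2a (-2.76, SE 0.39), Cacng5 (-2.50, SE 0.33), Pllp (-1.99, SE 0.31), Asic1 (-1.94, SE 0.22), Lrrn1 (-1.93, SE 0.31), Prr18 (-1.91, SE 0.28), Wnt7b (-1.86, SE 0.26), Ptgds (-1.84, SE 0.31) and Rcor2 (-1.84, SE 0.18) fell in 6 of 6 cultures too. The cultures' own Bmp6 RNA did not differ (46.0 FPKM ± 33.9 against 47.6 ± 40.8, adjusted p = 0.855), nor did Igfbp2 (log2 0.50, SE 0.34, adjusted p = 0.343).

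**Figure D3:**
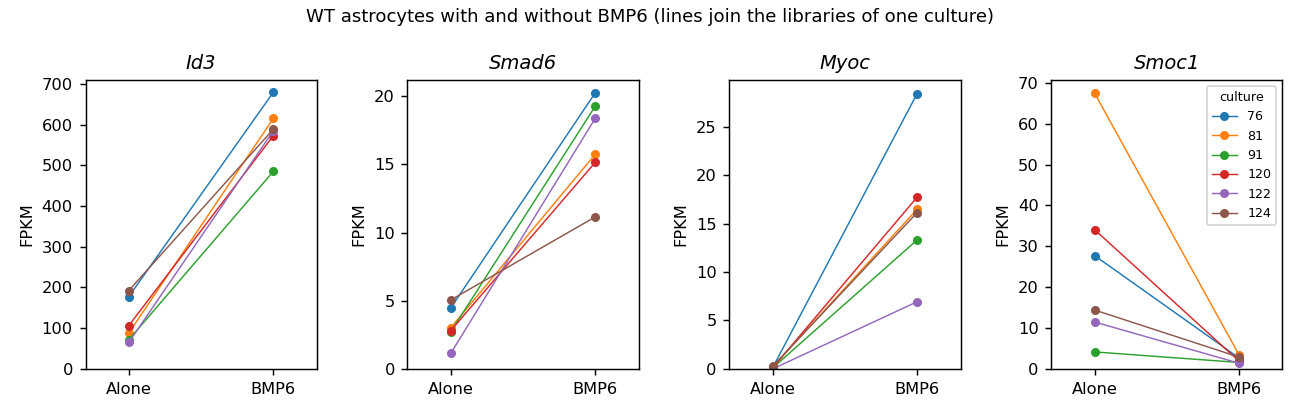
FPKM of Id3, Smad6, Myoc and Smoc1 in the Alone and BMP6 libraries of 6 WT cultures, with points for libraries and lines joining those of the same culture. In all 6 cultures Id3, Smad6 and Myoc were higher and Smoc1 was lower with BMP6.

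In all 1839 of 12185 genes responded to BMP6, 655 higher and 1184 lower. Over all tested genes, 966 did not overlap between the groups (7.93%, against 0.216% by chance). With each culture as a replicate block, 4321 genes passed (1385 higher and 2936 lower). Higher genes made up 35.6% of the calls, and 55.7% or 55.4% after median-of-ratios or quantile scaling. The count fell to 1041 without BMP6_81, 1115 without Alone_120, 1140 without BMP6_120 and 1078 without BMP6_122. It was 494 with 2 cultures (Alone_91, Alone_122 and their pairs) left out together, an alternative chosen after the data were seen. BMP target genes rose in 11 of 20 (camera adjusted p = 8.35e-10; 11 adjusted over the list alone). Cell cycle genes fell in 31 of 40 (adjusted p = 2.44e-13; 40 adjusted over the list alone and 40 with the culture as a block). Their summed expression was 484 FPKM ± 212 in Alone and 216 ± 56.8 with BMP6 (SD, n = 6), with Mcm7 at -1.08 (SE 0.15), Mcm6 at -0.94 (SE 0.18), Mcm5 at -1.54 (SE 0.31) and Mcm2 at -1.11 (SE 0.23). Without those 2 cultures 1 cell cycle gene was past the threshold, while the list still passed (adjusted p = 5.84e-07) at a median log2 of -0.78, against -1.10 with all cultures. Astrocyte markers rose in 5 of 37 (adjusted p = 1.87e-06; 3 adjusted over the list alone and 16 with the culture as a block). They included Sparcl1 (1.24, SE 0.17), Htra1 (0.96, SE 0.22), glutamine synthetase Glul (0.88, SE 0.23) and Id4 (1.97, SE 0.59, lost under 13 of 21 alternatives). Glycolysis genes rose in 7 of 22 (adjusted p = 8.99e-05; 7 higher and 1 lower adjusted over the list alone), with Pfkm at 0.69 (SE 0.10) and the glucose transporter Slc2a1 at 0.67 (SE 0.15). Interferon-response genes rose in 6 of 31 (adjusted p = 3.71e-06; 6 adjusted over the list alone), with Lgals3bp at 0.71 (SE 0.12). Cholesterol synthesis genes were higher in 21 of 24 (adjusted p = 0.000326), 0 of them past the threshold singly and 9 with the culture as a block. Without those 2 cultures the genes past the threshold were 2 higher and 1 lower of the astrocyte list, 2 of the glycolysis and 1 of the interferon list, and each list still passed (adjusted p = 0.00087 or less). With an estimated correlation none of these 6 lists passed (adjusted p = 0.153 for BMP target and glycolysis genes, 0.336 for cell cycle, astrocyte and interferon genes, 0.607 for cholesterol synthesis). The libraries were also split in 100 ways, the real one included. Medians as large came from 1 split for BMP targets and cell cycle genes and 4 for glycolysis. They came from 18 for astrocyte, 11 for interferon and 19 for cholesterol synthesis genes. These splits did not always part the 2 libraries of a culture, so differences between cultures entered them. They therefore cannot decide whether a response within cultures goes beyond chance for these lists. The other 17 lists did not pass (adjusted p = 0.0928 to 0.939), and the microglial list had too few measured genes to be tested. With the culture as a block, the synapse-regulating (camera adjusted p = 0.0229) and A1 lists (0.0339) passed as higher. The A1 list passed without Alone_81 (adjusted p = 0.0207), Alone_120 (0.0319) or BMP6_122 (0.0286), the matrix list without Alone_81 (0.0464) and the synapse-regulating list without BMP6_124 (0.0419).

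Bmp6 RNA averaged more in each disorder model than in WT, past the threshold only in DS, so the response to BMP6 was compared with each disorder's difference from WT over 12106 genes. Across genes, which are not independent replicates, the correlation was r = 0.0802 for FXS (Spearman 0.0462), 0.088 for RTT (0.0461) and 0.374 for DS (0.379). As large a value came from 52, 56 and 9 of 100 splits of the disorder and WT libraries, with a Benjamini-Hochberg value of 0.27 for DS over the 3 relations. With the cell cycle mean as a covariate in both fits, added after the data were seen, r was -0.167 for FXS, -0.0761 for RTT and 0.0485 for DS. Genes called in DS numbered 508 in this set and genes called with BMP6 1826. They shared 117 genes, 50 higher in both and 59 lower in both, against 12.0 and 27.6 for independent lists. Genes that vary together make up these lists, so no test of the overlap is given. Shared rises were Npvf, a neuropeptide precursor (log2 2.70, SE 0.56 in DS and 2.68, SE 0.27 with BMP6), Id3 and Smad9. Pcp4, which lies in the triplicated segment of chromosome 16, rose in each too, as did Pdgfd (1.11, SE 0.32 and 1.72, SE 0.21). The DS call of Pdgfd was lost under 14 of 20 alternatives. Others were Slc2a13 (0.54, SE 0.13 and 1.23, SE 0.16), Abca8a (1.02, SE 0.26 and 1.47, SE 0.20) and Prss23 (0.77, SE 0.18 and 0.90, SE 0.11, with 25.8% of its sequence shared). The netrin receptor Unc5a (-1.17, SE 0.25 and -1.41, SE 0.17) and Mcm7 fell in each.

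For the preparations, the first question was how immunopanned astrocytes change in culture. The glutamate transporter Slc1a2 fell by 2.52 on the log2 scale (SE 0.32, adjusted p = 0.000489), from 695.4 FPKM ± 338 in IP acute to 112.2 ± 15.7 in IP cultured (SD, n = 3 each). The intermediate filament gene Gfap rose from 347.6 FPKM ± 101 to 1283 ± 1110 (log2 1.60, SE 0.54, adjusted p = 0.0399, lost under 6 of 15 alternatives). The water channel Aqp4 (adjusted p = 0.0577) and Aldh1l1 (adjusted p = 0.108) did not pass. Blood and vessel genes nearly vanished in culture. Hbb-b1, Hbb-bs, Hbb-b2, Hbb-bt, Hba-a1 and Hba-a2, whose near-identical copies cannot be told apart, were listed at 0 in the cultured libraries, with Hbb-bs between 964.2 and 2917.8 FPKM in IP acute. The endothelial claudin Cldn5 went from 526.9 FPKM ± 140 to 0.011 ± 0.0191 (log2 -9.98, SE 0.20), with Slc38a5 beside it (-7.85, SE 0.18). Stimulus-induced genes fell with them, Fosb by 9.23 on the log2 scale (SE 0.53) and Nr4a1 from 1080 FPKM ± 410 to 5.00 ± 1.86. Among the largest rises were those of the contractile genes Acta2 (5.78, SE 0.74), Actg2 (5.17, SE 0.84) and Tagln (4.60, SE 0.58). Further rises were those of Rab26 (5.01, SE 1.15), Lpo (4.91, SE 0.60), Npvf (4.29, SE 0.65), Col8a1 (4.21, SE 0.69), the senescence gene Cdkn2a (4.26, SE 0.47) and the myelin genes Mag (4.69, SE 0.74) and Mog (4.33, SE 0.64).

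In total 6106 of 14101 genes differed, 2515 higher and 3591 lower in culture. Over all tested genes 7312 were without overlap (51.9%, against 10% by chance). After quantile scaling 61.4% of the calls were higher against 41.2%, and the median of all genes moved from -0.04 to 0.16 on the log2 scale. All 18 endothelial genes (camera adjusted p = 1.43e-13) and all 30 neuronal genes (adjusted p = 7.16e-11) fell, with Tie1, Pecam1, Kdr, Stmn2 and Tbr1 among them. So did 23 of 28 immediate early genes (adjusted p = 1.68e-11), such as Klf2, Klf4 and Atf3. Falls were also seen in 23 of 25 cholesterol synthesis genes (adjusted p = 5.58e-06) and 12 of 15 oligodendrocyte precursor genes (adjusted p = 0.00283), Pdgfra by -3.22 (SE 0.29). In the astrocyte list 19 of 39 fell and 3 rose (adjusted p = 0.00122), with Fgfr3 at -2.42 (SE 0.15) and Slc7a10 at -4.68 (SE 0.47). BMP targets fell in 14 of 24 (adjusted p = 0.000693; Smad7, Bambi and Eng) and BMP ligands, receptors and antagonists in 16 of 31 (adjusted p = 0.00512; Chrdl1 and Acvrl1). Further falls were in secreted synapse-regulating genes in 21 of 49 (adjusted p = 0.00924; Gpc6 and Vcan) and microglial genes in 8 of 22 (adjusted p = 0.00316; Csf1r and P2ry12). Upwards went 15 of 33 interferon-response genes (adjusted p = 1.61e-05; Ifit2 and Gbp2) and 9 of 18 oligodendrocyte genes (adjusted p = 0.00316). So did 5 of 13 pan-reactive genes (adjusted p = 0.049; Vim at 2.16, SE 0.24, and Cd44) and 7 of 28 SRF and YAP targets (adjusted p = 0.0472). Adjusted over the list alone the counts were 18, 30, 23, 24, 13, 20, 14, 17, 21, 8, 16, 10, 5 and 7 in the same order. Against the direction of their list went 2 BMP ligand, 3 synapse-regulating, 2 SRF and YAP, and 1 each of the precursor, interferon and oligodendrocyte genes past the threshold. Mean marker sums fell from 2422 to 99.5 FPKM for endothelial, 1870 to 127 for neuronal and 1277 to 274 for microglial genes. IP acute libraries thus held RNA of other cells. Whether the falls of the immediate early, cholesterol, BMP and synapse-regulating lists came from astrocytes or from those cells cannot be told apart. Without IP cultured 4 the oligodendrocyte (adjusted p = 0.0542), pan-reactive (0.145) and SRF and YAP lists (0.478) were lost, and cell cycle genes instead rose in 20 of 42 (adjusted p = 9.26e-06). The pan-reactive list was also lost without IP cultured 2 (0.0858) or IP acute 4 (0.17), and the SRF and YAP list without IP acute 4 (0.17). None of these 14 lists held with an estimated correlation (adjusted p = 0.463 or more), and the other 10 did not pass (adjusted p = 0.319 to 0.893).

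**Figure D4:**
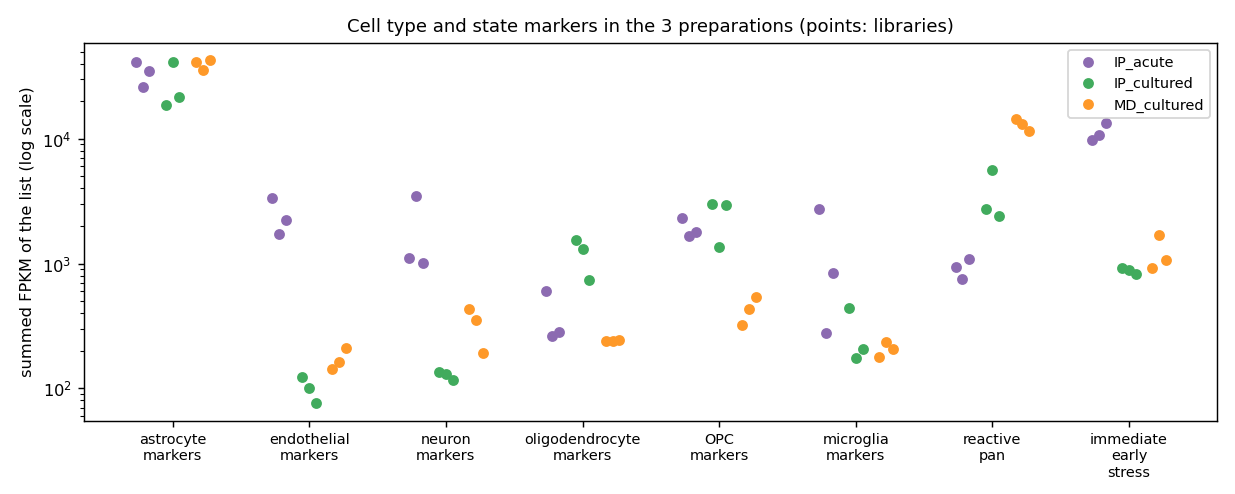
Summed FPKM, on a log axis, of 8 marker lists in each of the 9 libraries of IP acute, IP cultured and MD cultured astrocytes (n = 3 each). Endothelial sums averaged 2422 FPKM in IP acute, 99.5 in IP cultured and 172 in MD cultured, and pan-reactive sums 920, 3573 and 13030 FPKM.

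The second question was how the cultures differ between preparations. MD cultured astrocytes expressed the acute-phase gene Lcn2 at 1131 FPKM ± 632 against 4.10 ± 6.53 in IP cultured (log2 8.95, SE 0.99, adjusted p = 0.000335; n = 3 each). Complement C3 was at 195.4 ± 92.4 against 0.924 ± 0.691 (log2 7.12, SE 0.42). Fam107a (8.27, SE 0.65), Ccdc3 (7.81, SE 0.31), Dlk1 (6.95, SE 0.41), Sult1a1 (6.94, SE 0.42), Crym (6.56, SE 0.37), Wisp2 (5.58, SE 0.59), Defb1 (5.37, SE 0.74) and Folh1 (5.27, SE 0.33) were also higher. Gfap was higher, at 4415 FPKM ± 1420 (log2 2.07, SE 0.54, adjusted p = 0.0136, lost under 3 of 14 alternatives). Slc1a2 (adjusted p = 0.984), Aqp4 (adjusted p = 0.338) and Aldh1l1 (adjusted p = 0.244) did not differ beyond the spread. The oligodendrocyte lineage was lower in MD cultures, with Mbp at 7.67 FPKM ± 5.59 against 365.5 ± 204 (log2 -5.66, SE 0.96), Mag at -5.86 (SE 0.74) and Gpr17 at -6.04 (SE 0.67). Also lower were Bcas1 (-5.57, SE 0.51), Ugt8a (-4.96, SE 0.37), Pllp (-4.94, SE 0.38), Gatm (-5.06, SE 0.37), Sox10 (-4.86, SE 0.41), the pericyte gene Vtn (-6.84, SE 0.65) and Lpo (-4.93, SE 0.60). As lists, 15 of 18 oligodendrocyte genes (camera adjusted p = 4.06e-05; 17 adjusted over the list alone) and 12 of 15 precursor genes (adjusted p = 0.000191; 13) were lower. Reactive genes were higher, 8 of 13 pan-reactive (adjusted p = 0.000157; 8), and 8 of 13 of the A1 list (adjusted p = 0.000191; 8), which holds C3 and Fkbp5. So were 7 of 12 of the A2 list (adjusted p = 0.000763; 9), which holds Cd109 and Clcf1. The same held for 9 of 28 SRF and YAP targets (adjusted p = 0.00034; 8), 11 of 25 glycolysis genes (adjusted p = 0.000453; 11) and 14 of 24 BMP targets (adjusted p = 0.000542; 14). It held further for 18 of 61 extracellular matrix genes (adjusted p = 0.00346; 18), 9 of 28 immediate early genes (adjusted p = 0.00356; 9), and for 8 of 30 neuronal genes (adjusted p = 0.0053; 7) and 4 of 18 endothelial genes (adjusted p = 0.0427; 4). Lower past the threshold were 7 of these matrix genes, 3 BMP targets and 1 each of the A2, SRF and YAP, immediate early, neuronal and endothelial genes. None of these 12 held with an estimated correlation (adjusted p = 0.212 or more), and the other 12 did not pass (adjusted p = 0.0511 to 0.742). Marker sums averaged 1192 FPKM in IP cultured and 242 in MD cultured for oligodendrocyte genes, and 2447 and 430 for precursor genes. They were 127 and 325 for neuronal and 161 and 605 for ciliated cell genes. Whether the other differences came from astrocytes or from such cells cannot be told apart. Without IP cultured 4, cholesterol synthesis genes were lower in 18 of 25 (adjusted p = 0.00138) and the astrocyte list passed upwards (0.0344). SRF and YAP targets were then higher in 18 of 28 (median log2 1.42, against 0.85 with all libraries). The cell cycle median turned from 0.56 to -0.66 on the log2 scale, with 16 of 42 lower. The cell cycle list passed upwards without IP cultured 2 (0.0019), IP cultured 7 (0.00091) or MD cultured 3 (0.0104), and the interferon list without IP cultured 2 (0.0057). The endothelial list was lost without IP cultured 7 (0.0798) or MD cultured 3 (0.0978). In all 6454 of 14101 genes differed, 2317 higher and 4137 lower in MD, and 7955 of those tested were without overlap (56.4%, against 10% by chance). Higher genes made up 35.9% of calls, or 54.2% after median-of-ratios scaling, which moved the median of all genes from -0.16 to 0.04 on the log2 scale.

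Against IP acute, MD cultured astrocytes differed in 8478 of 14101 genes (2871 higher and 5607 lower), and 10177 were without overlap (72.2%, against 10% by chance). Lcn2 (log2 9.55, SE 0.99), the mucin Glycam1 (8.13, SE 0.44), C3 (8.05, SE 0.42) and Wisp2 (7.78, SE 0.59) were highest. They were followed by Ltbp2 (7.20, SE 0.53), Dlk1 (7.04, SE 0.41), Acta2 (6.61, SE 0.74), Tagln (5.96, SE 0.58) and Lmod1 (5.76, SE 0.71), with Defb1 at 90.5 FPKM ± 97.9 and listed at 0 in IP acute. Gfap was higher by 3.66 (SE 0.54) and Slc1a2 lower by -2.51 (SE 0.32). Cldn5 (-9.98, SE 0.20), Vtn (-8.46, SE 0.65), Gpr17 (-8.12, SE 0.67) and Pglyrp1 (-8.01, SE 0.25) were lowest after the haemoglobin genes. Pan-reactive genes rose in 12 of 13 (camera adjusted p = 3.56e-06; Vim, Serpina3n and Timp1), interferon-response genes in 21 of 33 (adjusted p = 1.25e-06) and SRF and YAP targets in 16 of 28 (adjusted p = 1.03e-05). Rises were found for the A1 list in 9 of 13 (adjusted p = 0.000424) and the A2 list in 7 of 12, with 4 lower (adjusted p = 0.0437). They were found for glycolysis genes in 14 of 25, with 4 lower (adjusted p = 0.00122), matrix genes in 26 of 61, with 15 lower (adjusted p = 0.00654) and cell cycle genes in 2 of 42 (adjusted p = 0.0412; Mki67 and Cenpe). Endothelial genes fell in 17 of 18 (adjusted p = 4.14e-07), immediate early genes in 23 of 28 (adjusted p = 4.02e-06) and precursor genes in 14 of 15 (adjusted p = 1.03e-05; Pdgfra by -7.28, SE 0.29). Falls were also found for cholesterol synthesis genes in 23 of 25 (adjusted p = 6.78e-05), neuronal genes in 24 of 30 (adjusted p = 9.82e-05) and microglial genes in 19 of 22 (adjusted p = 0.00353). Adjusted over the list alone the counts in this order were 12, 23, 17, 9, 7, 14, 26, 0, 17, 25, 14, 24, 24 and 20. Against the direction of their list went 2 interferon, 2 SRF and YAP, 1 A1 and 1 immediate early gene. As for IP cultured, whether the falls of the immediate early and cholesterol lists came from astrocytes or from other cells cannot be told apart. The A2 list was lost without IP acute 2 (adjusted p = 0.0888) or IP acute 4 (0.0647), and the matrix list without IP acute 4 (0.0728). The cell cycle list was lost without IP acute 2 (0.0866), MD cultured 1 (0.078) or MD cultured 2 (0.0695). None of these 14 lists held with an estimated correlation (adjusted p = 0.373 or more), and the other 10 did not pass (adjusted p = 0.0675 to 0.859). Higher genes made up 33.9% of calls, and 45.2% or 52.8% after median-of-ratios or quantile scaling, which moved the median of all genes from -0.24 to -0.06 or 0.06 on the log2 scale.

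The deposited table gave the authors' own fold changes for these 3 comparisons. Across genes they correlated with those computed here at r = 0.945 for IP cultured against IP acute, 0.933 for MD cultured against IP cultured and 0.956 for MD cultured against IP acute. At their adjusted p under 0.05 they listed 7288, 6818 and 10483 genes. Of these, 5651, 5334 and 7468 were also called here, and 5651, 5333 and 7467 had the same direction. For Gfap in IP cultured against IP acute the authors' table gave a log2 difference of 1.98 (adjusted p = 0.00426). For the leading rises of that comparison, Acta2 (log2 6.71) and Actg2 (10.03), the deposited adjusted p was 1. The same value is given wherever no fold change is, so it may stand for a missing one. Whether the authors tested these 2 genes cannot be told.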

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

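Among the tests in this part, those with array weights and with ciliated cell genes were chosen only after the result was seen.

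A library far from the others of its group was looked for in 186 group values, covering genes set beforehand and reported here and the list means in the disorder and BMP6 groups. It was found in 12, where chance gives about 1 in 20 groups (9 here). On the log2 scale, Igfbp2 was high in WT_22 (11.76, next 10.88), and Son (4.58, next 5.10) was low in FXS_31. As list means, oligodendrocyte genes were high in FXS_29 (2.29, next 1.18), immediate early genes in FXS_28 (3.33, next 2.98), neuronal genes in RTT_44 (2.05, next 1.70), A2 genes in DS_32 (4.27, next 3.92) and pan-reactive genes in BMP6_76 (4.48, next 4.02). Low values were found for glycolysis genes in RTT_20 (4.54, next 4.66), chromosome 17 segment genes (2.88, next 2.94) and SRF and YAP targets (4.44, next 5.64) in Alone_122, secreted synapse-regulating genes in BMP6_124 (3.87, next 4.05) and A2 genes in BMP6_81 (2.86, next 3.27).

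The disorders' effects differed by direct contrast in 3 genes between RTT and FXS, in 347 between DS and FXS and in 350 between DS and RTT. Of 100 splits, 4, 2 and 2 gave as many genes, with 1445, 447 and 717 in the highest other split. These shares are under 0.05, but they cannot exclude chance for genes other than those that the genotype sets. The 3 genes include Fmr1, which the genotype sets. The DS counts include genes of the triplicated segments such as App, and the splits were not run without these. Splits that call so many genes point to a structure of the samples other than the disorder.

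The DS differences outside the triplicated segments were weighed against technical sources. Of 509 such genes, 56% had another called gene within 1 Mb, above the 95th percentile of 1000 random draws (54.6%) but not above the highest (59.1%), while as many BMP6 genes gave 49.5%. Variants of the mouse strain around the segments or elsewhere therefore cannot be told apart from effects of the added copies, since the labels give no strain. Reads shared with similar genes were argued against as the whole cause: at least 20% of the sequence was shared in 26.1% of the genes lower by 2-fold or more (18 of 69) and in 18.6% of those higher (13 of 70). Over all tested genes the share was 12.4%, so such genes were enriched among the lower ones (odds ratio 2.5, Fisher's exact test p = 0.00162), and part of the falls may come from shared reads. Among the higher ones the odds ratio was 1.61 (Fisher's exact test p = 0.142). Chance was excluded for the count past the threshold over all genes, since 1 of 100 splits, the real one, gave 556 genes and the highest other gave 2. The count was 256 without DS 19 and 894 without DS 32. Of the 556, 523 were not placed in either segment, and the splits were not run on these alone. Chance was not excluded for genes at an unadjusted p under 0.05, since 7 of 100 splits gave as many as the real 2535. That number was 1645 without DS 19, and the highest other split gave 3411.

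The DS effect followed the BMP6 effect across genes (r = 0.374). Depth was argued against, since the upper tercile of genes by FPKM gave 0.385. With the cell cycle mean as a covariate in both fits the correlation was 0.0485, so a shared fall in proliferation may account for it, and 9 of 100 splits of the DS and WT libraries gave as large a value (highest other 0.444), so chance was not excluded. Whether BMP signalling lowers proliferation in DS cultures was not tested.

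FXS had 2493 genes at an unadjusted p under 0.05 where 639 were expected, and 1601 without FXS 17. Low depth was argued against, since 16.9% of genes in the upper tercile by FPKM were below 0.05 (24% in the lower tercile), and so were the libraries of high FPKM sum, since 2151 genes were found without WT 33 and FXS 31 (636 expected). In 1 of 100 splits, the real one, as many genes were found (highest other 2286). That share is under 0.05 with all libraries in, by a narrow margin. No splits were run without FXS 17, where the count was 1601, or with the ciliated cell covariate below, so chance stays open there. For genes past the threshold 1 of 100 splits gave as many (1 gene, highest other 0). That gene is Fmr1, which the genotype sets, so the count tells nothing of other genes. With array weights 2 of 100 splits gave as many (4159 genes, highest other 4319), where another division of the same libraries called more genes and points to their structure. With the mean of ciliated cell genes as a covariate 943 genes were below 0.05 (639 expected), so a share of ciliated cells that differs between the groups may account for much of the excess, although the covariate and the group go together in part. A biological effect of the lost Fmr1 stays open.

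For RTT, 6 of 100 splits called as many genes as the real one (1, highest other 1147), 11 of 100 gave as many at an unadjusted p under 0.05 (1342, highest other 3206; 2110 without WT 22, 874 without WT 33, 848 without WT 34), and 5 of 100 with array weights (2944, highest other 4351), so chance was not excluded for these counts, and splits calling so many genes point to a structure of the samples. For BMP6, 1 of 100 splits, the real one, gave 1839 genes (highest other 0). With each culture as a block, 1 of the 32 splits that part all 6 pairs gave 4321 (highest other 0), so chance was excluded. For the preparations 1 of 10 splits, the real one, gave 6106, 6454 and 8478 genes (highest other 0 in each), and 10 splits are too few for a share under 0.05.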

How the results depend on the processing

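Tests with array weights, with a covariate, without WT 33, FXS 31 and DS 32, without 2 BMP6 cultures (Alone_91, Alone_122 and their pairs) or without IP cultured 4, and the other pseudocounts and scalings of the comparisons between disorders, were chosen only after the data were seen. Over the alternatives, 6601 of 6861 values of the 521 named-gene results (96.2%) kept their direction and side of the threshold, 173 lost the threshold, 68 gained it, 0 reversed and 19 moved. For the 239 list results these were 3195 of 3574 (89.4%), 140, 84, 2 and 153. A change of sign with neither value past the threshold counted as moved, and correlations within 20% as unmoved. Apart from those set beforehand, the named genes were chosen by their change or p in these same data. Their share unmoved is therefore partly fixed in advance. The 2 reversals were of the direction relative to the other genes, with the cell cycle covariate in DS. They were in pan-reactive genes (median log2 -0.16 before and -0.34 after) and cell cycle genes (-0.80 and -0.013), the latter by construction, and no median changed sign. With an estimated correlation 0 lists passed for FXS, RTT, BMP6, each preparation comparison and RTT against FXS, and 2 for DS against WT, FXS and RTT. A minimum of 2-fold left 150 genes for DS, 289 for BMP6, and 3036, 2855 and 4727 for IP cultured against IP acute, MD against IP cultured and MD against IP acute, by construction. For the other changes the cause was not tested. Without a filter FXS gave 2 genes and RTT 3 lists. With a filter at 5 FPKM DS gave 353 genes and 5 lists and RTT 0 lists, from fewer genes tested. Either scaling gave 2 lists for RTT. With only the 2 groups in the fit FXS gave 209 genes and DS 305. Array weights gave 4159 genes for FXS, 2944 for RTT, 2886 for DS, 3740 for BMP6, 10482 for IP cultured against IP acute and 10800 for MD against IP cultured. Without WT 33, FXS 31 and DS 32 there were 4 genes and 3 lists for RTT and 994 genes for DS. The cell cycle covariate gave 12 genes for FXS, 2 for RTT, and 164 genes and 13 lists for DS, and correlations with the BMP6 effect of -0.167 for FXS, -0.0761 for RTT and 0.0485 for DS. The mean of ciliated cell genes as a covariate kept the BMP target list past the threshold for FXS (adjusted p = 0.0171) and DS (2.84e-05). Without those 2 cultures BMP6 gave 494 genes, with fewer samples. The replicate block gave 4321 genes for BMP6 and 3907 for IP cultured against IP acute; it ended the call of Gfap in the latter (adjusted p = 0.129) and, with BMP6, brought among others Srebf2, Tm7sf2 and Pmvk and the synapse-regulating (adjusted p = 0.0229) and A1 lists (0.0339) past the threshold. It changed no other call reported here. To look for pairing, each library was taken as its deviation from the mean of its group. Correlations of these deviations between libraries of the same culture number were 0.41 to 0.777 in BMP6, each the best match. For IP acute and IP cultured they were 0.0303, -0.051 and 0.0853, which shows no pairing, and whether the numbers pair samples stays open. Leaving out single libraries gave 1 to 14 genes for FXS (14 without WT 22), 1 to 4 genes and 1 to 4 lists for RTT (4 genes without WT 22), 256 to 894 genes for DS (without DS 19 and DS 32), 1041 to 2010 for BMP6, and 0 to 9 genes common to disorders (9 without RTT 40). Correlations with BMP6 then ran from -0.0267 to 0.189 for FXS, 0.0332 to 0.178 for RTT and 0.272 to 0.443 for DS. Ddx3y as a covariate left 1 gene past the threshold for FXS and RTT and 472 for DS, while genes at an unadjusted p under 0.05 went from 1342 to 867 for RTT. The microglial list could not give a value for BMP6. Depth was lowest in WT (10.2 M reads), which may widen the spread of low genes there, though this was not tested.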

Other observations

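The tests with ciliated cell genes were chosen only after the result was seen; that of Bmp6 RNA against its targets was set before.

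Genes of ciliated cells, which line the ventricles and are not astrocytes, varied widely between cultures. Summed over 14 measured genes they ran from 180 to 644 FPKM in WT (mean 375 ± 177 SD, n = 6), 453 to 1600 in FXS (831 ± 440), 155 to 893 in RTT (378 ± 299) and 282 to 659 in DS (498 ± 175). In the preparations they averaged 37.6 ± 12.3 in IP acute, 161 ± 139 in IP cultured and 605 ± 229 in MD cultured (n = 3 each). In the BMP6 set they ran from 35.7 to 508 in Alone and from 38.2 to 418 with BMP6. Over the 6 cultures the mean log2 values of the Alone and BMP6 libraries went together (Pearson r = 0.922, exact permutation p = 0.00278 over 720 pairings, two-sided; Spearman 1; 0.959 without the 2 farthest cultures). The highest of these genes were Foxj1 (118.7 FPKM ± 37.5 in WT and 219.7 ± 68.9 in FXS) and Dynlrb2 (63.6 ± 36.5 and 147.1 ± 89.7), and none of the list is in another list used here. Per the labels the disorder and BMP6 cells were immunopanned, which would remove other cells. A share of ciliated cells that differs between cultures may explain this.

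Bmp6 RNA and the mean of its 22 measured target genes rose and fell together over the 22 disorder and WT libraries once centred by group (Pearson r = 0.874, permutation p = 2e-05, Benjamini-Hochberg 4e-05; Spearman 0.817, p = 5e-05; 100000 permutations, two-sided). Without the 2 farthest libraries, RTT_43 and WT_26, r was 0.853. Ciliated cell genes went with both (r = 0.745 with Bmp6 and 0.676 with the targets). With their mean taken out of both, r was 0.753 (0.679 to 0.805 with any library left out), which argues against such cells as the whole cause. Cultures may thus set their BMP target genes by their own Bmp6, a hypothesis that other factors shared by both would meet as well.

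Myelin gene Mbp ranged from 0.387 to 84.6 FPKM over the disorder and WT libraries, chosen here after its values were seen.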
